A study of Homo sapiens with 4 samples.

How the data were processed

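Single-cell RNA was measured in 12 cultures of microglia-like cells from the H9 line, in 4 conditions of 3 cultures: Ctrl, Sema, LPS and SemaLPS. Per the labels' protocols, cells were collected with actinomycin D, each culture was stained with its own hashtag antibody against CD298 and β2-microglobulin, and about 2000 cells per culture were pooled. The pool was divided into 2 libraries made with 10x 3' v3.1 chemistry. The deposited values are UMI counts per gene and per hashtag for each barcode called as a cell, with no normalization per the file headers. The headers name Cell Ranger 6.0.1, while Cell Ranger 3.0.2, Seurat 4.1.1 and hg38 are named per the submitters' processing notes. The annotation release is not given in the sources used here. The files hold 36601 genes and 12 hashtags. GENCODE v29, used here for positions, holds 34616 (94.58%) of these gene IDs.

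Barcodes were assigned to cultures from their hashtag counts in each library, in the manner of HTODemux. A threshold was set for each hashtag at the 99th percentile of a negative binomial fitted to background barcodes, from k-means with 13 clusters on centred log ratios. The background was the cluster with the lowest mean of that hashtag, after leaving out its top 0.5%. The thresholds were unequal, from 10 counts for LPS-3 in both libraries to 309 for Sema-3 in library 1. In library 1 the median count of barcodes led by the hashtag was 304 for LPS-3, 353 for Ctrl-3 and 1354 for Sema-3. Another definition of the background, all barcodes outside the hashtag's highest cluster, was tried first and replaced after its call counts but no gene test had been seen; it is kept as an alternative. Of 28943 barcodes, 21929 carried 1 hashtag, 6517 (22.52%) carried more and 497 carried none. The pool was nominally of 24000 cells. Cells with 1 hashtag were kept with at least 1000 genes and at most 10% mitochondrial UMIs, which left 15043 (7812 and 7231 in the libraries). Between 60.49 and 79.36% of a culture's cells were kept, and the share over 10% mitochondrial UMIs, 20.18 to 39.12%, was lower in LPS-treated and in number 1 cultures. Cells were normalized to 10000 UMIs, and clustered with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5, seed 0). Sizes of clusters were not compared between conditions.

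Counts were summed per culture over both libraries and tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood F test), all 12 cultures in 1 fit, with Benjamini-Hochberg adjustment at 0.05 over 15098 genes. The culture is the replicate. Standard errors are the log2 fold change divided by the square root of F, an approximation. The contrasts were Sema against Ctrl, LPS against Ctrl, SemaLPS against LPS, SemaLPS against Sema, and their interaction. The 17 fixed gene lists and 14 marker lists were tested with camera in limma 3.58.1, with an inter-gene correlation preset at 0.01 and with an estimated one, adjusted over lists within a contrast. The fixed lists are homeostatic microglia, disease-associated microglia, NF-κB and cytokines, interferon, antigen presentation, γ-secretase complex, γ-secretase substrates, Notch targets, cholesterol synthesis, lipid efflux, lysosome, TGF-β response, immediate-early and heat shock, unfolded protein response, glycolysis and hypoxia, cell cycle, and mitochondrial transcripts; 11 genes are in 2 lists. Lists, contrasts, thresholds and the rule for named genes were chosen before the data were examined. That rule takes, per contrast, the 10 largest rises and the 10 largest falls among genes past the threshold whose cultures do not overlap (10% of genes by chance) and with at least 20 CPM, and from each list up to 3 members with the smallest adjusted p. Some genes that the rule takes are not reported here. With the block, the same direction in all 3 pairs replaced the overlap criterion, a change chosen after seeing the data.

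The planned fit has no block. Same-numbered cultures deviated together: over 5280 genes, correlations of deviations from the condition means lay between 0.44 and 0.742 for the same number and between −0.546 and 0.165 for other numbers, and each of the 12 cultures correlated best with its own number. The labels do not say what a number stands for, so the pairing comes from the data. Results of the paired fit, with the number as a block, are given beside the planned ones, and were added as results of their own after seeing the data. Simulated counts were drawn 1 time per contrast from the paired fit's own coefficients and dispersions, with 200 genes changed. The paired model thus held by construction, so that its higher recovery cannot show which fit suits the real cultures. For Sema against Ctrl, with 14968 genes run, the unpaired fit recovered 86.7% (26 of 30) of 1.25-fold changes at 20 or more CPM. The paired fit recovered 100%, and 0 of 99 and 13 of 137 calls were false. For SemaLPS against LPS (14989 genes) the shares were 72.5 and 100% of 40 such genes, with 0 of 115 and 13 of 162 calls false. For the interaction (14992 genes) they were 22.2 and 83.3% of 36 such genes, with 0 of 64 and 16 of 139 calls false, so that the paired fit called more unchanged genes than its nominal 5%.

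Alternatives were DESeq2 1.42.0 size factors and Wald test, no filter on low counts, the replicate block, only the 2 conditions compared, each library alone, at least 500 genes and at most 20% mitochondrial UMIs, the highest hashtag at least 2 times the next with at least 10 counts, and each culture left out in turn. Chosen after seeing the data were cells outside the proliferating clusters, cells outside clusters 4, 7 and 8, and the wider hashtag background. For scores per cell, cells were thinned to 10000 UMIs. Background RNA in droplets was not analysed here. Other tools were numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, anndata 0.12.19 and matplotlib 3.10.9.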

Results

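Gene expression was measured in single microglia-like cells made from H9, an established human embryonic stem cell line, by way of monocyte-like precursors matured in a medium built on TGF-β, IL-34 and cholesterol. The study asked how expression changes when γ-secretase is blocked. This membrane protease cuts the stubs that remain after receptors such as Notch shed their outer domains, and releases their intracellular parts. The study also asked whether bacterial lipopolysaccharide (LPS), a strong signal that does not need γ-secretase, overrides any such change. The 12 cultures fell into 4 conditions with 3 cultures each: vehicle (Ctrl), the γ-secretase inhibitor semagacestat at 2 µM for 22 h (Sema), LPS at 200 ng/mL for the last 6 h (LPS), and both (SemaLPS). Each culture carried its own hashtag antibody, the cells were pooled, and the pool was divided into 2 droplet libraries. The libraries held 28943 barcodes and 900761329 unique molecular identifiers (UMIs). Of these barcodes, 15043 were single cells of known culture that passed the filters. A culture had between 1053 cells (Ctrl-1) and 1664 cells (Sema-3), between 30433501 (Ctrl-1) and 51783420 (SemaLPS-2) UMIs, and a median of 27396.5 to 31452.5 UMIs per cell. The cultures are of 1 line, so p-values measure the spread between these cultures.

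The cells carried the transcripts of macrophages and microglia in every condition. In Ctrl cultures the complement gene C1QA stood at 422 ± 38.2 CPM (SD, n = 3; TMM-scaled UMI counts relative to library size), TREM2, a lipid-sensing receptor of microglia, at 505 ± 46.9, and CSF1R, the receptor for M-CSF and IL-34, at 175 ± 2.61. Of 14 marker lists for cell types, 7 had at least 3 measurable genes. The other 7 (mast cell, granulocyte precursor, erythroid, megakaryocyte, endothelial, pluripotent and neural) had fewer, and their most abundant gene, TUBB3, reached 8.10 CPM without TMM scaling. Clustering gave 11 groups of cells. Cells of LPS-treated cultures made up nearly all of clusters 0 and 1 (3102 and 3457 cells, of which 17 were Ctrl or Sema), and cells without LPS nearly all of clusters 2 and 3 (3515 and 2047 cells, of which 58 had LPS). Clusters 6, 9 and 10 (849, 1043 and 134 cells) were proliferating-like, with all 8 markers of dividing cells over 2-fold higher than in other cells. Cluster 5 (108 cells) was led by interferon-induced genes such as IFIT1 and RSAD2, and cluster 4 (689 cells) by CRABP2, TIMP3, FBP1 and MMP7. The small clusters 7 and 8 (67 and 32 cells) were shallow, at 4798 and 5076.5 UMIs per cell in the median, and were not named.

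Blocking γ-secretase without LPS left most transcripts near their Ctrl level, and lowered HES1 and EGR3. HES1, a transcriptional repressor switched on by Notch, stood at 1.59 ± 0.159 CPM in Sema cultures against 3.00 ± 0.211 in Ctrl cultures (SD, n = 3 each), a log2 fold change of −0.91 (SE 0.13). EGR3, a transcription factor of the early growth response family, stood at 5.43 ± 0.725 against 8.97 ± 0.25, a log2 fold change of −0.73 (SE 0.10). For both genes each Sema culture lay below each Ctrl culture after scaling. HES1 was read from 53 to 90 UMIs per Sema culture and 95 to 107 per Ctrl culture, and EGR3 from 176 to 274 and 289 to 306. HES1 (ENSG00000114315) lies on chromosome 3 at 194136145 to 194138732, and EGR3 (ENSG00000179388) on chromosome 8 at 22687659 to 22693302, both protein-coding in GENCODE v29 on GRCh38, which is not necessarily the annotation the authors used. HES1 belongs to a list fixed in advance, while EGR3 falls outside the rule for named genes and was chosen after its values were seen. These were the 2 of 15098 genes that passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.0468 for each). No gene rose in this test, and 1076 genes had an unadjusted p under 0.05. Chance alone would put a share of about 0.05 of all genes there, so that such a count does not by itself show an effect. DESeq2's Wald test called 16 genes and gave neither HES1 nor EGR3 an adjusted p. With 1 culture left out, HES1 kept its direction but lost its call in 10 of 12 cases, all but those without SemaLPS-2 or SemaLPS-3. EGR3 lost its call in 9 cases, those without any of Ctrl-1, Sema-1, LPS-1, SemaLPS-1, Ctrl-2, LPS-2, Ctrl-3, Sema-3 or LPS-3. Over all alternatives, the log2 fold change ranged from −1.10 to −0.80 for HES1 and from −0.92 to −0.49 for EGR3, with adjusted p up to 0.616 for each.

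Cultures of the same number deviated together, and with the number as a block 513 genes passed in the same comparison (277 rose and 236 fell). HES1 fell by 0.90 on the log2 scale in that fit (adjusted p = 0.0023). DUSP1, a phosphatase that switches off MAP kinases, fell by 0.40 (SE 0.06, adjusted p = 0.00244), against adjusted p = 0.0964 without the block. Large falls were seen for SLC16A10, a transporter of aromatic amino acids (−0.99, SE 0.13), SRGN, the core protein of granule proteoglycans (−0.67, SE 0.09), and the DNA-binding protein HIVEP1 (−0.51, SE 0.08). Of the named genes that rose at 20 or more CPM in all 3 pairs, the largest rises that kept their call without any 1 culture were of EBI3, a cytokine subunit (0.50, SE 0.08), FOLR2, the folate receptor of tissue macrophages (0.38, SE 0.06), BIN1, which shapes membranes (0.36, SE 0.06), PCNA, the sliding clamp of DNA replication (0.34, SE 0.06), and the crystallin CRYBB1 (0.33, SE 0.05). Of the 35 named genes past the threshold in this fit, 15 kept their call without each culture in turn, among them the genes just given and HES1, DUSP1, AIF1, SPP1, CD9 and CTSB. CXCL8, a neutrophil chemokine, passed at −0.42 (SE 0.11, adjusted p = 0.048) but did not pass without any of Sema-1, SemaLPS-1, Ctrl-2, Sema-2, SemaLPS-2, Ctrl-3 or Sema-3, and stood at 0.10 when cells were assigned by the ratio of their top hashtags. Of the 17696 cells kept by that ratio, 2693 carried more than 1 hashtag by the main rule. The number of genes passing was 169 without Ctrl-2, 157 without Sema-2, 90 without Ctrl-3 and 68 without Sema-3. The excess of rises did not hold under several alternatives: 188 rose and 267 fell with DESeq2 size factors, 98 and 168 by DESeq2's Wald test, 426 and 468 with the 2 conditions alone, 84 and 126 in library 1, 65 and 97 in library 2, 117 and 169 by the ratio of the top hashtags, 64 and 93 without Sema-2, 173 and 177 without SemaLPS-2, 28 and 62 without Ctrl-3, and 28 and 40 without Sema-3.

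By gene group, camera with its preset correlation put the cell cycle and homeostatic microglial lists higher and the lists of disease-associated microglia and of the early stress response lower with the inhibitor without LPS, while most of their genes did not pass and no list passed with an estimated correlation. With the block, 5 of 16 cell cycle genes rose and none fell (10 adjusted over the list alone), among them PCNA, MCM3 and MCM5. The list's median log2 fold change was 0.23, with camera adjusted p = 1.12e-11, and adjusted p = 0.167 with an estimated correlation. Of 21 homeostatic microglial genes, 7 rose and 0 fell (10 and 1 adjusted over the list alone), such as AIF1, a calcium-binding marker of microglia (0.25, SE 0.03), the purinergic receptor P2RY13 (0.52, SE 0.08) and the fractalkine receptor CX3CR1 (0.33, SE 0.06). This list had adjusted p = 5.89e-09, and adjusted p = 0.116 with an estimated correlation. With the block and 1 culture left out, P2RY13 (0.478) and JUND (−0.202) lost their calls without Sema-3, CX3CR1 without Ctrl-2 (0.332), Ctrl-3 (0.286) or Sema-3 (0.236), MCM3 without Ctrl-2 (0.29) or Ctrl-3 (0.288), and MCM5 without Ctrl-2 (0.266), Sema-2 (0.237), Ctrl-3 (0.23) or Sema-3 (0.316). Of 22 genes of disease-associated microglia, 5 fell and 0 rose (11 and 0 adjusted over the list alone), including osteopontin (SPP1, −0.21, SE 0.03), the tetraspanin CD9 (−0.29, SE 0.04) and the protease CTSB (−0.18, SE 0.03), with adjusted p = 5.89e-09, and adjusted p = 0.146 with an estimated correlation. Of 16 immediate-early and heat shock genes, 5 fell and 0 rose (8 and 0 adjusted over the list alone), including DUSP1 and JUND, with adjusted p = 2.52e-07, and adjusted p = 0.146 with an estimated correlation. Without the block, none of the cell cycle, homeostatic, disease-associated or immediate-early genes passed edgeR's test, where 1076 of all genes had an unadjusted p under 0.05 and DESeq2 called 16. The 4 lists then had camera adjusted p = 0.000195, 0.000195, 0.00268 and 7.97e-06, and adjusted p = 0.845, 0.101, 0.845 and 0.101 with an estimated correlation. In that fit the cell cycle list (median 0.20) did not pass without Ctrl-2 (0.042), and the disease-associated list (median −0.09) did not pass without Sema-1 (−0.034) or Ctrl-3 (−0.021). Between replicate numbers, the cell cycle list was higher by a median of 0.51, the homeostatic list higher by 0.089 (adjusted p = 0.00224, beside 0.082 with the inhibitor and the block) and the disease-associated list lower (−0.20) in the number 1 cultures.

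**Figure D1:**
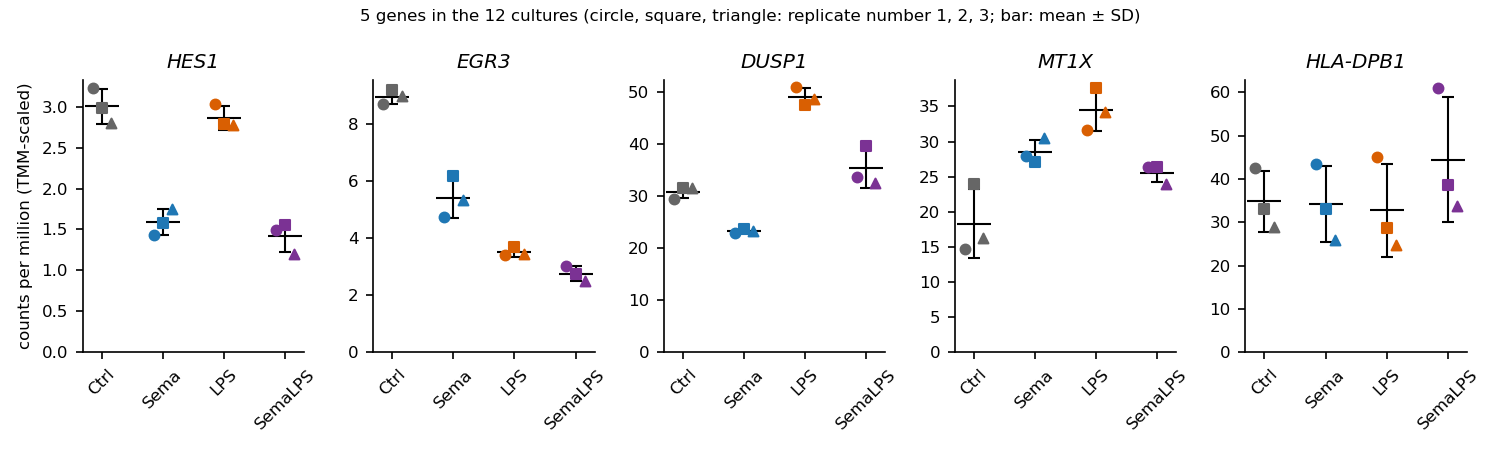
TMM-scaled CPM (vertical axes, linear) of HES1, EGR3, DUSP1, MT1X and HLA-DPB1 in each of the 12 cultures, by condition; circles, squares and triangles are replicate numbers 1, 2 and 3, and bars give the mean and SD of 3 cultures. HES1 stood at 3.00 ± 0.211 in Ctrl, 1.59 ± 0.159 in Sema, 2.87 ± 0.148 in LPS and 1.42 ± 0.190 in SemaLPS cultures.

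The Notch pathway and the enzyme itself were read separately. Among 8 measurable Notch target genes, HES1 fell and 7 did not pass, in both fits (3 fell with the block, adjusted over the list alone, and 1 without it). The glycosyltransferase gene LFNG stood at −0.30 (SE 0.09, adjusted p = 0.0777) and DTX1 at −0.45 (SE 0.15, adjusted p = 0.128) with the block. The list had camera adjusted p = 0.0114 without and 0.0319 with the block, and adjusted p = 0.101 and 0.169 with an estimated correlation, and did not pass without Ctrl-3 (median 0.03 against −0.19, without the block). None of the 6 subunit genes of γ-secretase passed, at a median log2 fold change of −0.04 (adjusted p = 0.438, and adjusted p = 0.845 with an estimated correlation). None of 24 genes for known substrates of the protease passed (median −0.03, adjusted p = 0.284, and adjusted p = 0.845 with an estimated correlation), though as a list they passed lower without Ctrl-1 (−0.08, adjusted p = 0.0316). Each of these 0 counts stands beside 1076 unadjusted p-values under 0.05 over all genes and 16 calls by DESeq2. The glycolysis and hypoxia list had camera adjusted p = 0.00241, and adjusted p = 0.348 with an estimated correlation, and did not pass without Sema-2 (median −0.027) or Ctrl-3 (−0.014). HIF1A stood at −0.29 (SE 0.07, adjusted p = 0.444). With the block HIF1A fell (adjusted p = 0.0141), but not without Ctrl-2, Sema-2, Ctrl-3 or Sema-3. The lysosome list (median −0.047) passed lower with the block (2 of 22 genes fell, or 6 fell and 2 rose adjusted over the list alone; adjusted p = 0.0167, and adjusted p = 0.167 with an estimated correlation), and passed without it (adjusted p = 0.209 with all cultures) when Ctrl-1 (−0.064) or Sema-3 (−0.07) was left out. In the number 1 cultures the lysosome list stood at a median of −0.108 (camera adjusted p = 8.83e-13), beside −0.047 with the inhibitor. Without the block, the cholesterol synthesis list (median 0.032) passed without Ctrl-1 (0.064) or Sema-3 (0.103), the NF-κB list (−0.075) without Sema-2 (−0.121) and the interferon list (0.041) without Sema-3 (0.098).

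LPS remade the transcriptome, with cytokine and chemokine genes higher and homeostatic microglial genes lower. CXCL8 went from 33.0 ± 5.77 to 1153 ± 116 CPM, IL1B from 91.3 ± 5.68 to 2082 ± 246, and SOD2, a mitochondrial antioxidant enzyme under NF-κB, from 297.5 ± 26.2 to 4428 ± 71.5 (SD, n = 3 each). At 20 or more CPM, the largest rises were of TNIP3, an inhibitor of NF-κB signalling (log2 fold change 6.25, SE 0.18, adjusted p = 4.68e-12), the chemokine CCL8 (6.21, SE 0.31), LINC02605 (6.18, SE 0.19), the hyaluronan-binding TNFAIP6 (5.72, SE 0.12) and the chemokine CCL20 (5.52, SE 0.11). CCL8 stood below 1 CPM in Ctrl cultures. At 20 or more CPM, the largest falls were of the leukotriene receptor CYSLTR1 (−2.75, SE 0.19), the amino acid transporter SLC7A8 (−2.63, SE 0.13), the myeloid transcription factor CEBPA (−2.62, SE 0.13), RGCC (−2.60, SE 0.34), the signalling inhibitor SPRY2 (−2.57, SE 0.11) and GPR34, a lipid receptor of microglia (−2.55, SE 0.06, adjusted p = 8.74e-13). In all, 8935 of 15098 genes passed (4577 rose and 4358 fell), of which 955 rose and 1315 fell over 2-fold. TNIP3 lies on chromosome 4 at 121131408 to 121227466 and GPR34 on chromosome X at 41688973 to 41697277. Of 69 named genes past the threshold in this comparison, 67 kept their call without each culture in turn. The exceptions were APH1A, at 0.11 without Ctrl-3, and NCSTN, at −0.13 without LPS-1, Ctrl-2, Ctrl-3 or LPS-3, both subunits of γ-secretase.

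Among the lists, 35 of 36 NF-κB and cytokine genes rose with LPS and 1 fell, the same adjusted over the list alone, at a median log2 fold change of 3.96 (adjusted p = 1.18e-94, and adjusted p = 0.000548 with an estimated correlation). Of 21 homeostatic genes, 13 fell and 3 rose, again the same adjusted over the list alone, with a median of −1.04 (adjusted p = 2.07e-07, and adjusted p = 0.0222 with an estimated correlation, or 0.0507 with the block). Interferon-induced genes rose in 23 of 28 cases and fell in 1 (24 and 2 adjusted over the list alone). They included CXCL10 (5.44, SE 0.35) and IRF1 (0.93, SE 0.06), with adjusted p = 0.014, and adjusted p = 0.643 with an estimated correlation. The list (median 1.07) did not pass without LPS-3 (0.832, adjusted p = 0.0658), a culture in which its genes summed to 872.2 CPM, against 527.7 in LPS-1 and 409.6 in LPS-2. Glycolysis and hypoxia genes rose in 13 of 14 cases, such as HIF1A (1.13, SE 0.07), LDHA (0.64, SE 0.04) and ADM (2.74, SE 0.20), with adjusted p = 0.000461, and adjusted p = 0.187 with an estimated correlation. Of 8 Notch target genes 6 rose, the same adjusted over the list alone, and HES1 did not pass (−0.07, adjusted p = 0.655). The list stood higher at adjusted p = 0.014, and adjusted p = 0.129 with an estimated correlation, but did not pass with the block (adjusted p = 0.0527). DTX4 (2.99, SE 0.07) and HES4 (2.16, SE 0.29) led it. Among lists with members on both sides, 8 antigen presentation genes rose, such as the peptide transporter TAP1 (2.30, SE 0.05), and 3 fell, such as HLA-DMB (−1.31, SE 0.08), with adjusted p = 0.104, and adjusted p = 0.643 with an estimated correlation (adjusted p = 0.0403 without LPS-2). NOTCH1 (−1.11, SE 0.06) and CSF1R (−0.93, SE 0.04) fell among the substrates of the protease. EGR3 fell by 1.36 (adjusted p = 7.2e-08) and DUSP1 rose by 0.67.

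The remaining lists did not pass as groups in LPS against Ctrl without the block and with all 12 cultures. Of TGF-β response genes 2 rose and 8 fell, ID1 by 2.94 and TGFBR1 by 1.04 (adjusted p = 0.0762). This list passed lower with the block (adjusted p = 0.0289, and adjusted p = 0.337 with an estimated correlation), and without it when Ctrl-3 (adjusted p = 0.0448) or LPS-3 (adjusted p = 0.02) was left out. Of 11 genes of the unfolded protein response 7 rose and 1 fell, XBP1 by 1.41 among the former (adjusted p = 0.0842). Of 20 cholesterol synthesis genes 6 rose and 6 fell (adjusted p = 0.871), with LSS at 1.62, and of 11 genes of lipid efflux 5 rose and 1 fell (adjusted p = 0.274), with PLTP at 1.18. Of 22 lysosomal genes 5 rose and 10 fell (adjusted p = 0.864), and of 22 disease-associated genes 8 rose, CD83 by 2.81, and 9 fell (adjusted p = 0.87). Of 16 cell cycle genes 7 fell (adjusted p = 0.274), of 13 mitochondrially encoded transcripts 10 rose (adjusted p = 0.293), and of 16 immediate-early and heat shock genes 7 rose and 4 fell (adjusted p = 0.293). The mitochondrial share of UMIs per kept cell, which is not TMM-scaled, went the other way. Its median was 7.793, 7.832 and 8.038% in LPS-1 to LPS-3, against 8.242, 8.394 and 8.341% in Ctrl-1 to Ctrl-3. The substrates of γ-secretase had 8 up and 10 down (adjusted p = 0.199), and its subunits 2 up and 1 down (adjusted p = 0.628). Adjusted over the list alone, these counts stood at 2 and 8, 7 and 2, 8 and 7, 5 and 1, 5 and 10, 8 and 9, 0 and 6, 11 and 0, 7 and 4, 8 and 10, and 2 and 1. With an estimated correlation the adjusted p of these lists lay between 0.511 and 0.963. Monocyte markers moved in the same comparison: 5 of 8 rose and 1 fell, S100A9 from 167 ± 12.3 to 881 ± 32.7 CPM (adjusted p = 0.000331, and adjusted p = 0.0214 with an estimated correlation). Of 12 macrophage and microglia markers 8 fell and 3 rose (adjusted p = 0.000331, and adjusted p = 0.0285 with an estimated correlation). The lists for dendritic cells (3 rose and 2 fell, adjusted p = 0.08), epithelium (3 fell, adjusted p = 0.0721), lymphocytes (adjusted p = 0.784), dividing cells (2 fell, adjusted p = 0.689) and stroma (1 fell, adjusted p = 0.76) did not pass as groups.

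Under the inhibitor, LPS had nearly the effect that it had without it. In SemaLPS against Sema cultures TNIP3 rose by 6.37 (SE 0.18), CCL8 by 6.04 (SE 0.28), TNFAIP6 by 5.77 (SE 0.11) and CXCL8 by 5.50 (SE 0.12). CEBPA (−2.81, SE 0.13), CYSLTR1 (−2.73, SE 0.19), GPR34 (−2.55, SE 0.06) and MERTK, a receptor for the engulfment of dying cells (−2.26, SE 0.12), fell. NF-κB and cytokine genes had a median log2 fold change of 4.1 with the inhibitor and 3.96 without it, with 35 of 36 rising and 1 falling in each case (adjusted p = 3.27e-89, and adjusted p = 0.00109 with an estimated correlation). Homeostatic genes fell in 16 of 21 cases and rose in 3 (adjusted p = 7.5e-08, and adjusted p = 0.0213 with an estimated correlation, or 0.0568 with the block), the same adjusted over the list alone. Glycolysis and hypoxia (adjusted p = 3.53e-05), Notch target (0.0154), antigen presentation (0.02), unfolded protein response (0.02) and interferon lists (0.0418) also passed higher and the TGF-β list lower (0.0494), with adjusted p between 0.0952 and 0.646 with an estimated correlation. The interferon list did not pass with the block (adjusted p = 0.0634) or without SemaLPS-3 (median 0.654 against 0.727), and the TGF-β list (median −0.736) did not pass without Ctrl-1 (−0.744), LPS-1 (−0.734), SemaLPS-1 (−0.705), SemaLPS-2 (−0.791) or SemaLPS-3 (−0.739). In this comparison 9245 genes passed (4670 rose and 4575 fell), 945 rising and 1310 falling over 2-fold. Of the genes past the threshold, 7989 were shared with LPS against Ctrl, where independent lists would share 5471, and 7987 of them had the same sign. Across the 5280 genes with at least 20 CPM, which are not independent replicates, the LPS effects without and with the inhibitor had Pearson's r = 0.992, Spearman's rho = 0.979 and a slope of 0.992. All 454 of these genes that changed over 2-fold kept their sign, with a median ratio of 0.996 between the effects. The comparisons share no culture.

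**Figure D2:**
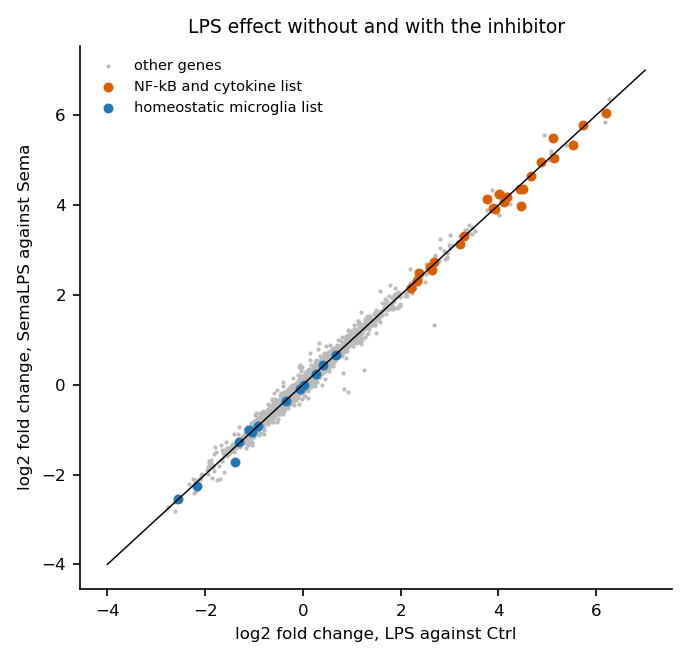
Log2 fold change with LPS in cultures without the inhibitor (horizontal axis) against that in cultures with it (vertical axis), for the 5280 genes with at least 20 CPM; each point is 1 gene from a fit to 12 cultures, NF-κB and cytokine genes and homeostatic genes are coloured, and the line marks equal effects. The points follow the line, at r = 0.992 across genes.

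In LPS-treated cultures, blocking γ-secretase again lowered HES1, and it lowered DUSP1. HES1 stood at 1.42 ± 0.190 CPM in SemaLPS cultures against 2.87 ± 0.148 in LPS cultures (SD, n = 3 each), a log2 fold change of −1.01 (SE 0.13, adjusted p = 0.0354). DUSP1 (ENSG00000120129, chromosome 5, 172768090 to 172771195) stood at 35.3 ± 3.81 against 49.0 ± 1.69, a log2 fold change of −0.47 (SE 0.06, adjusted p = 0.0356). EGR3 stood at −0.34 (SE 0.11, adjusted p = 0.84). HES1 and DUSP1 were the 2 genes past edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. No gene rose, 827 had an unadjusted p under 0.05, and DESeq2's Wald test called 9, with DUSP1 among them (adjusted p = 8.44e-07) and no adjusted p for HES1. The 827 are little more than the share of 0.05 of all genes that chance alone would give. HES1 lost its call in 9 of 12 cases with 1 culture left out, all but those without a Ctrl culture, and DUSP1 in 8, all but those without a Ctrl culture or SemaLPS-2. Over all alternatives the log2 fold change ranged from −1.08 to −0.80 for HES1, with adjusted p up to 0.969, and from −0.56 to −0.42 for DUSP1, with adjusted p up to 0.614.

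With the replicate number as a block, 281 genes passed in this comparison (191 rose and 90 fell). HES1 (adjusted p = 0.000737) and DUSP1 (adjusted p = 0.000389) fell in it. The genes that rose included TYMS, which makes thymidylate for DNA synthesis (0.62, SE 0.09), the linker histone HIST1H1C (0.50, SE 0.08), BIN1 (0.44, SE 0.06), the sulfotransferase GAL3ST4 (0.42, SE 0.06), and MHC class II genes. Of the latter, HLA-DPB1 (ENSG00000223865, chromosome 6, 33075926 to 33087201) rose by 0.44 (SE 0.06), HLA-DRA by 0.44 (SE 0.07), HLA-DPA1 by 0.43 (SE 0.07) and HLA-DMB by 0.43 (SE 0.04). Falls at 20 or more CPM included those of bone sialoprotein (IBSP, ENSG00000029559, chromosome 4, 87799581 to 87812435; −0.97, SE 0.11), GLDN (−0.61, SE 0.08), RAMP1, a partner of the CGRP receptor (−0.53, SE 0.05), the growth factor PDGFA (−0.40, SE 0.05), the urokinase receptor PLAUR (−0.34, SE 0.04) and the cytokine IL1B (−0.33, SE 0.05). Of 43 named genes past the threshold, 29 kept their call without each culture in turn, among them each gene of this paragraph. The number of genes passing was 134 without LPS-1, 125 without SemaLPS-1 and 126 without SemaLPS-2. Without LPS-2, 110 rose and 131 fell.

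With the block 13 of 17 lists passed in the inhibitor comparison under LPS, 6 higher and 7 lower, and none of them with an estimated correlation. Among those higher, 10 of 17 antigen presentation genes rose, the same adjusted over the list alone (median 0.35, adjusted p = 3.16e-20, and adjusted p = 0.0662 with an estimated correlation). All 9 MHC class II genes among them, grouped after the list had been seen, rose, at 0.22 to 0.65 with a median of 0.43 (the median of their single-gene SEs was 0.06). Of 20 cholesterol synthesis genes 9 rose (11 adjusted over the list alone), such as FDPS (0.24, SE 0.03), ACAT2 (0.25, SE 0.04) and HMGCS1 (0.24, SE 0.04), with adjusted p = 2.02e-17, and adjusted p = 0.0844 with an estimated correlation. Of 16 cell cycle genes 5 rose (11 adjusted over the list alone), with adjusted p = 1.66e-17, and adjusted p = 0.0844 with an estimated correlation. Of 11 genes of the unfolded protein response 3 rose (6 adjusted over the list alone), with adjusted p = 7.61e-05, and adjusted p = 0.0844 with an estimated correlation. The 3 each lost their call with single cultures left out: HYOU1 without LPS-1, SemaLPS-1, LPS-2 or SemaLPS-2 (0.151 to 0.21), SDF2L1 without these or SemaLPS-3 (0.133 to 0.19), and HSPA5 without SemaLPS-1, LPS-2, SemaLPS-2, LPS-3 or SemaLPS-3 (0.077 to 0.121). In the number 1 cultures the antigen presentation (0.272), cholesterol synthesis (0.127) and unfolded protein response lists (0.072) stood higher too, beside 0.347, 0.132 and 0.124 with the inhibitor. Disease-associated genes fell in 5 of 22 cases (8 adjusted over the list alone), SPP1 by 0.23 and CD9 by 0.25 and TREM2 by 0.18, with adjusted p = 5.16e-07, and adjusted p = 0.123 with an estimated correlation. Without the block that list (median −0.05, adjusted p = 0.0124) did not pass without SemaLPS-1 (0.016) or LPS-3 (0.005). Homeostatic genes rose in 4 of 21 cases (5 rose and 2 fell adjusted over the list alone), including AIF1 (0.23, SE 0.03) and OLFML3 (0.22, SE 0.04), with adjusted p = 0.00149, and adjusted p = 0.137 with an estimated correlation. Of 36 NF-κB and cytokine genes 1 rose (CCL8, 0.36, SE 0.04) and 2 fell (IL1B and CCL20), or 2 and 3 adjusted over the list alone, with adjusted p = 0.00693, and adjusted p = 0.423 with an estimated correlation. CCL20 lost its call without LPS-1 (−0.267), LPS-2 (−0.233), SemaLPS-2 (−0.265), LPS-3 (−0.204) or SemaLPS-3 (−0.14). Without the block the homeostatic list did not pass without LPS-1 (median 0.033), SemaLPS-1 (0.039) or LPS-3 (0.049), and the NF-κB list without LPS-1 (−0.04) or SemaLPS-3 (−0.022). Without the block none of the antigen presentation genes passed edgeR's test (5 rose adjusted over the list alone), where 827 of all genes had an unadjusted p under 0.05 and DESeq2 called 9. HLA-DMB then stood at 0.43 (SE 0.08, adjusted p = 0.166), with the list at adjusted p = 5.86e-07, and adjusted p = 0.129 with an estimated correlation.

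The other lists past the threshold in this comparison with the block held few genes that passed. Of these, the γ-secretase substrate (median −0.116, camera adjusted p = 2.21e-05) and lipid efflux lists (−0.066, adjusted p = 0.00101) were also lower in the number 1 cultures. With the inhibitor and the block both stood at −0.039. Immediate-early and heat shock genes stood lower (1 of 16 fell, or 6 adjusted over the list alone; adjusted p = 2.96e-06, and adjusted p = 0.111 with an estimated correlation), as did Notch targets (1 of 8 fell, the same adjusted over the list alone; adjusted p = 0.0193, and adjusted p = 0.132 with an estimated correlation). Lipid efflux genes (1 of 11 rose and 3 fell, or 1 and 4 adjusted over the list alone; adjusted p = 0.0135, and adjusted p = 0.208 with an estimated correlation) and γ-secretase substrates (1 of 24 fell, or 3 adjusted over the list alone; adjusted p = 0.019, and adjusted p = 0.152 with an estimated correlation) stood lower too, and did not pass without the block (adjusted p = 0.0831 and 0.081), except for lipid efflux without SemaLPS-2 (median −0.095 against −0.038) and the substrates without LPS-1 (−0.064 against −0.036), SemaLPS-2 (−0.097) or SemaLPS-3 (−0.069). Of 28 interferon-induced genes none passed edgeR's test (1 fell adjusted over the list alone; adjusted p = 0.025, lower, and adjusted p = 0.558 with an estimated correlation), and of 13 mitochondrially encoded transcripts none did (adjusted p = 0.0135, higher, and adjusted p = 0.443 with an estimated correlation), in the fit without the block as well, where 827 of all genes had an unadjusted p under 0.05 and DESeq2 called 9. Without the block the interferon list (median −0.11) did not pass without LPS-1 (−0.064), SemaLPS-2 (0.005) or LPS-3 (0.039), and the mitochondrial list (median 0.02) did not pass without LPS-1 (0.03), Ctrl-2 (0.021), LPS-2 (0.016), SemaLPS-2 (0.027) or SemaLPS-3 (0.019). The TGF-β list (median −0.02) passed without LPS-1 (−0.057), the lysosome list (0.022) without SemaLPS-1 (0.042) or LPS-3 (0.046), and the glycolysis and hypoxia list (0.014) without SemaLPS-3 (0.051).

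**Figure D3:**
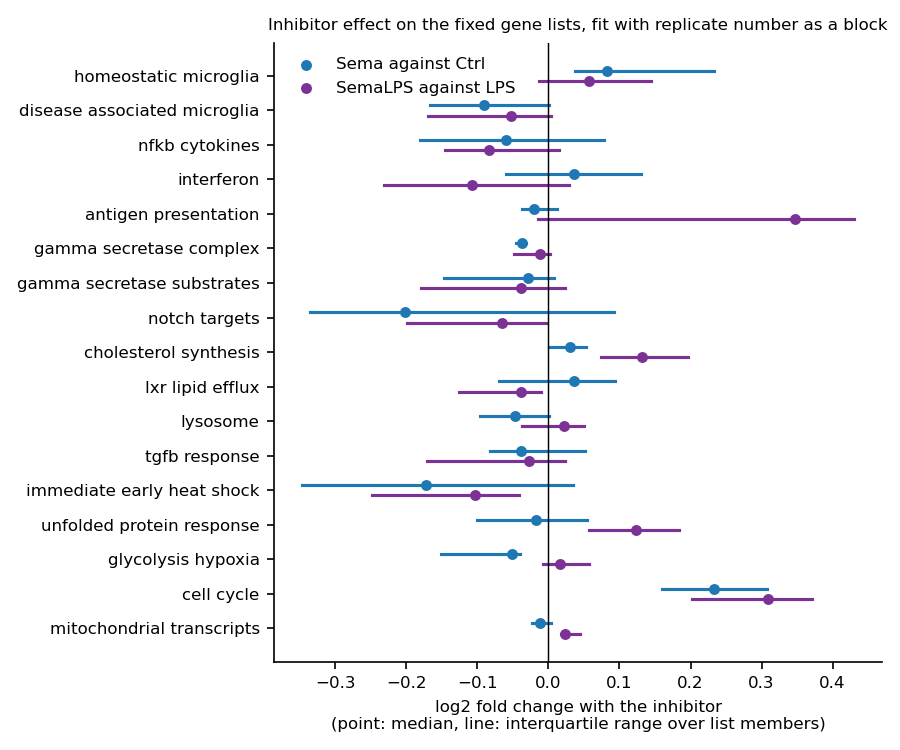
Median log2 fold change with the inhibitor (horizontal axis) of the genes of each fixed list (vertical axis), without and with LPS, from the fit with the replicate number as a block to 12 cultures; bars span the quartiles of the list's genes. The antigen presentation list stood at −0.02 without LPS and 0.35 with it.

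Across LPS levels the inhibitor effects resembled each other. With the block, 86 genes passed at both levels, where independent lists would share 9.55, and 84 of them had the same sign (57 higher, against 3.50, and 27 lower, against 1.41). Over 5280 genes, which are not independent replicates, the inhibitor effects without and with LPS had Pearson's r = 0.485 and Spearman's rho = 0.422. HES1 fell by 0.90 without and 1.01 with LPS, DUSP1 by 0.40 and 0.47, SPP1 by 0.21 and 0.23, and AIF1 rose by 0.25 and 0.23, with the block. Inhibitor effects and the difference of the number 1 cultures from the others also correlated across these genes, at r = 0.428 and 0.555 between opposite LPS levels.

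The interaction asked whether LPS changes what the inhibitor does. For HES1 the inhibitor effect differed between LPS levels by −0.10 (SE 0.18, adjusted p = 1), and for EGR3 by 0.38 (adjusted p = 1). No gene passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 550 genes had an unadjusted p under 0.05, and DESeq2 called 1. The 550 are fewer than the share of 0.05 of 15098 genes that chance alone would give. With the block 10 genes passed, 8 with a higher inhibitor effect under LPS and 2 with a lower one. With the looser cell filter these were 2 and 6, with 4 of the 8 genes shared with the 10, in library 1 alone 0 and 4, by the ratio of the top hashtags 0 and 1, without Ctrl-2 1 and 5, and without SemaLPS-1 or Sema-3 0 and 1. The 8 were HLA-DPB1 (0.48, SE 0.08), HLA-DRB1 (0.41, SE 0.06), DOP1B (0.40, SE 0.07), HLA-DMB (0.37, SE 0.06), the amino acid transporter SLC38A2 (0.35, SE 0.06), SOCS6 (0.30, SE 0.05), the copper transporter SLC31A1 (0.30, SE 0.05) and MMD (0.27, SE 0.04). HLA-DRB1 (ENSG00000196126) lies at 32578769 to 32589848 and HLA-DMB (ENSG00000242574) at 32934629 to 32941070 of chromosome 6. MT1X, a metal-binding metallothionein (ENSG00000187193, chromosome 16, 56682424 to 56684196), rose with the inhibitor without LPS (0.66, SE 0.10) and fell with it under LPS (−0.43, SE 0.10), a difference of −1.09 (SE 0.14, adjusted p = 0.0152). Each other measured metallothionein differed in the same direction as MT1X, but none of them passed. IBSP differed by −0.97 (SE 0.16, adjusted p = 0.0366). Each of the 10 genes lost its call in at least 5 of the 12 cases with 1 culture left out, and the count ranged from 0 to 41. It stood at 29 without Ctrl-1, 0 without Sema-1, 1 without SemaLPS-1, 6 without Ctrl-2, 16 without Sema-2, 0 without LPS-2, SemaLPS-2 or Ctrl-3, 1 without Sema-3, 20 without LPS-3 and 41 without SemaLPS-3. Without the block, the count was 1 without Ctrl-2. The rise of MT1X without LPS did not pass without Sema-3 (0.565), and stood at 0.07 in library 2 alone and at 0.27 without clusters 4, 7 and 8, and its fall under LPS did not pass without LPS-1, LPS-2, SemaLPS-2, LPS-3 or SemaLPS-3.

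By list, the antigen presentation genes had the largest median interaction, 0.37 (adjusted p = 0.000883, and adjusted p = 0.466 with an estimated correlation), which did not pass without LPS-2 (0.308, adjusted p = 0.13). With the block 3 of 17 passed over all genes, and 10 rose and 1 fell adjusted over the list alone. The MHC class II genes stood at a median of −0.02 with the inhibitor without LPS and 0.43 under LPS. The interferon list had a lower inhibitor effect under LPS (median −0.22, adjusted p = 0.0154, and adjusted p = 0.793 with an estimated correlation), which did not pass without LPS-1 (−0.153), Ctrl-2 (−0.17), Sema-2 (−0.104), SemaLPS-2 (−0.101) or LPS-3 (−0.022). In LPS-3 the interferon-induced IFI6 stood at 192 CPM, against 37.9 in LPS-1 and 33.2 in LPS-2. With the block 9 lists passed: antigen presentation (adjusted p = 9.29e-15), cholesterol synthesis (2e-08), unfolded protein response (0.000425), glycolysis and hypoxia (0.000304), mitochondrial transcripts (0.00488) and lysosome (0.0175) with a higher inhibitor effect under LPS, and lipid efflux (0.00473), interferon (0.00759) and homeostatic genes (0.0474) with a lower one, at adjusted p between 0.141 and 0.742 with an estimated correlation. Apart from antigen presentation, no member of these lists passed over all genes, of which 10 of 15098 did. Adjusted over the list alone, 4 cholesterol synthesis, 3 unfolded protein response, 2 lysosomal and 1 glycolysis and hypoxia gene were higher. So adjusted, 3 lipid efflux genes and 1 homeostatic gene were lower, and no interferon or mitochondrial gene passed. Without the block and with 1 culture left out, the cell cycle list (median 0.073) passed lower without Ctrl-1 (−0.157) and higher without Ctrl-2 (0.278). The disease-associated list (0.03) passed without Ctrl-1 (0.065) or SemaLPS-1 (0.08), the homeostatic list (−0.024) without Ctrl-1 (−0.06) or SemaLPS-1 (−0.063), the lysosome list (0.041) without Ctrl-1 (0.057), SemaLPS-1 (0.076), Sema-2 (0.054), Sema-3 (0.052) or LPS-3 (0.066), the lipid efflux list (−0.1) without Ctrl-3 (−0.128), and the NF-κB list (−0.01) without SemaLPS-2 (−0.062).

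A 1.5-fold effect of the inhibitor was excluded for most abundant genes. Among 5280 genes with at least 20 CPM, the 95% interval of the log2 fold change excluded a 1.5-fold change in 5181 (98.1%) for Sema against Ctrl, in 5203 (98.5%) for SemaLPS against LPS, and in 5146 (97.5%) for the interaction. These shares come from the fit without the block. The intervals hold for single genes, without adjustment for their number, and genes below 20 CPM are not among them. With the block and over all genes tested, 44 genes past the threshold changed over 1.5-fold in Sema against Ctrl and 27 in SemaLPS against LPS. Genes as low as HES1, at about 3 CPM, were measured from 44 to 109 UMIs per culture.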

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

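The tests of dividing cells, of the metallothionein family and of the MHC class II genes against the replicate axis, as well as the 32 splits that part every pair, were chosen only after the result was seen. For the axis across all genes, the resemblance of the lists had been seen before the test. Several results differed between LPS levels by the interaction of inhibitor and LPS. With the replicate block these were HLA-DPB1 (0.476), HLA-DRB1 (0.408), DOP1B (0.40), HLA-DMB (0.367), SLC38A2 (0.354), SOCS6 (0.301), SLC31A1 (0.297), MMD (0.265), IBSP (−0.971) and MT1X (−1.087). Without it they were the medians of 6 lists: antigen presentation (0.368), cholesterol synthesis (0.114), unfolded protein response (0.095), glycolysis and hypoxia (0.071), mitochondrial transcripts (0.049) and interferon (−0.219), none of which passed with an estimated correlation. With 1 culture left out, antigen presentation did not pass without LPS-2 (0.308), cholesterol synthesis without Ctrl-1 (0.064) or Sema-3 (0.042), glycolysis and hypoxia without Ctrl-3 (0.045), mitochondrial transcripts without Sema-1 (0.037), LPS-1 (0.057), Ctrl-2 (0.053), Sema-2 (0.032), LPS-2 (0.021), SemaLPS-2 (0.055), Ctrl-3 (0.033) or SemaLPS-3 (0.03), and interferon without LPS-1 (−0.153), Ctrl-2 (−0.17), Sema-2 (−0.104), SemaLPS-2 (−0.101) or LPS-3 (−0.022). For the interaction, chance could not be excluded for the lists without the block or for genes and lists with it. Without the block, 28 of 60 splits drawn gave at least the 6 lists of the real one, with a highest other of 11. The real split had 0 genes by edgeR (550 with an unadjusted p under 0.05, 1 by DESeq2), which any of the 60 splits must reach, so that its count decides nothing; the highest other was 303. With the block, 3 of 60 gave at least 10 genes and 3 at least 9 lists, with highest others of 10 and 10. The split with 303 genes sets the number 1 cultures against the number 2 cultures at both LPS levels and points to the difference between replicate numbers; it gave 0 genes with the block. Among all 32 splits that part every pair, 4 gave as many as the real 10, the others 86, 47 and 1029. The last is the average inhibitor effect. The splits with 86 and 47 swap pairs at 1 LPS level only, so that most pair differences still add up to that average effect. The 32 splits thus hold the inhibitor effect itself, and cannot say how often chance alone gives 10 genes. For lists, 8 of these 32 gave at least the real 9, with a highest other of 10 and 9 for the average inhibitor effect.

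By list medians, cell cycle and homeostatic genes stood higher and disease-associated genes lower with the inhibitor at both LPS levels, except that under LPS the disease-associated median without the block was 0.016 without SemaLPS-1 and 0.005 without LPS-3, and that the cell cycle genes summed to 836.7 CPM in Sema-1 against 856.5 in Ctrl-1. The inhibitor effect at 1 LPS level correlated with the difference of number 1 from the other numbers at the other level at r = 0.428 and 0.555 across 5280 genes, which is consistent with treated cultures lying elsewhere on the axis that separates the numbers. The correlation of inhibitor effects between levels went from 0.485 to 0.163 after regression on the numbers; an inhibitor that moves cells along the same axis would give this too, so the biological explanation stays open. Without the proliferating clusters the cell cycle median kept at most 0.292 of its size in either contrast, but these clusters are the cells with high cell cycle genes, so that more dividing cells and higher levels in each dividing cell cannot be told apart by it. The homeostatic and disease-associated medians kept at least 0.703 of theirs in Sema against Ctrl, which argues against the cells of these clusters as the main cause for those lists without LPS. Dividing cells outside these clusters may remain, and the contrast under LPS was not tested in this way.

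MHC class II genes stood higher with the inhibitor under LPS. With the 5% of cells highest in them left out of every culture, their median log2 fold change was 0.459 against 0.43, which argues against a small number of cells with very high levels. The replicate axis and an inhibitor effect under LPS cannot be told apart: the median without LPS lay −1.89 standard errors from what the axis would give (−0.022 against 0.116) and under LPS 0.97 (0.43 against 0.321). These standard errors are built from medians of single-gene SEs and take the ratio along the axis as exact, so that they are approximate. An earlier bound for this test, a median without LPS under 0.05, was met by −0.022; it was replaced after that value was seen, because the pattern lies under LPS, so the explanation is left open.

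MT1X stood higher with the inhibitor without LPS and lower with it under LPS. The summed counts of the metallothionein family had an interaction of −1.408 (SE 0.251, adjusted p = 0.0593) beside −1.087 (SE 0.141) for MT1X, and its member MT2A stood at −1.385 (SE 0.249, adjusted p = 0.063), so that reads shared with a changing paralog and a change of MT1X itself cannot be told apart. Every measured member had a negative interaction with the block, from −3.313 (MT1M) to −0.619 (MT1F), though only MT1X passed. Without LPS, MT2A (0.809, adjusted p = 0.0369), MT1E (1.893, adjusted p = 0.0271), MT1M (2.224, adjusted p = 0.0483) and the sum (0.823, adjusted p = 0.0264) passed higher too. The direction was thus not particular to MT1X. The rise of MT1X without LPS stood at 0.07 (adjusted p = 0.928) in library 2 alone and 0.268 (adjusted p = 0.257) without clusters 4, 7 and 8, and did not pass without Sema-3 (0.565). These alternatives leave open whether a small group of cells carries it, and no biological explanation beyond the interaction was tested.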

How the results depend on the processing

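The alternatives without the proliferating clusters, without clusters 4, 7 and 8 and with a wider hashtag background, and those of the paired fit, were chosen only after the result was seen. Of 362 counts of genes and lists, 269 stayed within 1.5 times the reported one. For single genes and lists outside the leaving out of cultures, 6195 comparisons kept direction and side of the threshold, 156 passed newly, 341 no longer passed and 4 turned direction; with 1 culture left out these were 6388, 70, 282 and 4. The cause was not tested for any change below, except that fewer cells or cultures, or more genes tested, follow from the alternative's own construction. Counts of genes past the threshold in the LPS contrasts stayed within 1.5 times under each alternative, unlike their counts of lists: with 1 culture left out 8184 to 9007 genes passed in LPS against Ctrl and 8434 to 9381 in SemaLPS against Sema, and with the block 9139 to 9949 and 9407 to 10348.

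Sema against Ctrl had 2 genes. The replicate block gave 513, DESeq2's Wald test 16, no filter on low counts 26, the 2 conditions alone 0, library 1 and library 2 0 each, the looser cell filter 1, cells outside proliferating clusters 0 and outside clusters 4, 7 and 8 4, and left-out cultures 0 to 4. It was 0 without Sema-1, LPS-1, SemaLPS-1, LPS-2, Ctrl-3, Sema-3 or LPS-3, 1 without Ctrl-2 or Sema-2 and 4 without SemaLPS-3. SemaLPS against LPS had 2. In the same order of alternatives the counts were 281, 9, 12, 0, 0, 1, 0, 1 and 5, the ratio rule for hashtags gave 0, and left-out cultures 0 to 3 (0 without Sema-1, LPS-1, SemaLPS-1, Sema-2, LPS-2, Sema-3 or SemaLPS-3, 1 without SemaLPS-2 or LPS-3). The interaction had 0 genes by edgeR (550 with an unadjusted p under 0.05), 10 with the block, 1 by DESeq2, 1 with no filter, and 0 to 1 with cultures left out (1 without Ctrl-2). The counts of 0 in the inhibitor contrasts are edgeR's, beside 1076 and 827 unadjusted p-values under 0.05 and 16 and 9 calls by DESeq2.

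With the paired fit, Sema against Ctrl had 513 genes, 2 without the block, 266 by DESeq2, 969 with no filter, 894 with the 2 conditions alone, 210 and 162 in library 1 and 2, 286 by the ratio rule, 240 outside proliferating clusters, and 68 to 593 with cultures left out (169 without Ctrl-2, 157 Sema-2, 90 Ctrl-3, 68 Sema-3). SemaLPS against LPS had 281, 2 without the block, 805 with no filter, 92 in library 1, 166 by the ratio rule, and 125 to 354 with cultures left out (134 without LPS-1, 125 SemaLPS-1, 126 SemaLPS-2). The interaction had 10, 0 without the block (edgeR), 27 by DESeq2, 220 with no filter, 4 in library 1, 1 by the ratio rule, 6 with the wider background, and 0 to 41 with cultures left out (29 without Ctrl-1, 0 Sema-1, 1 SemaLPS-1, 6 Ctrl-2, 16 Sema-2, 0 LPS-2, 0 SemaLPS-2, 0 Ctrl-3, 1 Sema-3, 20 LPS-3, 41 SemaLPS-3). The block moved no count of genes in the LPS contrasts by over 1.5 times.

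Lists past the threshold were 6, 5, 11, 8 and 6 over the contrasts (Sema against Ctrl, LPS against Ctrl, SemaLPS against LPS, SemaLPS against Sema, interaction). With an estimated correlation they were 0, 2, 0, 2 and 0, and 0, 1, 0, 1 and 0 with the block too. LPS against Ctrl had 10 with no filter, SemaLPS against LPS 7 in library 2, SemaLPS against Sema 4 in library 1 and the interaction 3 in library 2. With cultures left out the ranges were 3 to 9 (3 without Ctrl-3), 5 to 6, 9 to 11, 6 to 8 and 4 to 9. Directions, for lists those of camera, turned under the ratio rule for CXCL8 (0.10) and CCL4 (0.191) in the paired fit and for the NF-κB list (0.155), all in Sema against Ctrl, and outside proliferating clusters for HIST1H1B in SemaLPS against LPS (−0.294). The ratio rule kept 2693 cells, of 17696, that carried more than 1 hashtag by the main rule, and whether they cause its turns was not tested. With 1 culture left out directions turned in SemaLPS against LPS for disease-associated genes (0.016 without SemaLPS-1, range −0.085 to 0.016) and the interferon list (0.039 without LPS-3, range −0.257 to 0.039), and in the interaction for the cell cycle (−0.157 without Ctrl-1, adjusted p = 0.0112, against 0.278 without Ctrl-2, adjusted p = 0.00253, range −0.157 to 0.278). In the interaction the interferon list turned by camera's direction, at a median of −0.022 without LPS-3 (range −0.357 to −0.022). Medians of lists past the threshold that changed sign while camera's direction did not were those of Notch targets in Sema against Ctrl without Ctrl-3 (0.03 against −0.191), and in SemaLPS against LPS of disease-associated genes without LPS-3 (0.005) and interferon without SemaLPS-2 (0.005). Alternatives for the case of no hashtag counts were not run, because cells could be assigned to cultures. Depth was not varied. On data simulated from the paired fit for Sema against Ctrl, 30.5% of the smallest simulated changes were recovered over all genes and 86.7% at 20 or more CPM. With the block these were 43.2 and 100%, in data that follow that fit by construction. Low genes such as HES1, with 44 to 109 UMIs per culture, were thus the harder to call.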

Other observations

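The test of the share of cycling cells and the splits below were chosen before their results were seen, and the levels of marker genes and of interferon-high cells after. Cells with a high cell cycle score were more frequent with the inhibitor. After thinning to 10000 UMIs per cell, the share of cells with a score of at least 10 was 12.6 ± 4.6% in Ctrl, 16.4 ± 2.79% in Sema, 7.94 ± 1.53% in LPS and 9.99 ± 2.79% in SemaLPS cultures (SD, n = 3). It was higher with the inhibitor in 6 of 6 pairs of same-numbered cultures, by 2.94 ± 1.74 points in the mean, with an exact sign-flip p = 0.031, the smallest that 6 pairs can give. This test takes the 6 pairs as independent, though they come from 3 replicate numbers, each present at both LPS levels. The pairing itself came from the data. The score sums the genes of the cell cycle list in the same cells in which that list was tested. The share is thus another view of that result and not separate evidence for it. Within either LPS level alone, 3 of 3 pairs were higher, with an exact sign-flip p = 0.25, the smallest that 3 pairs can give. Without thinning the shares were 20.5, 25.0, 13.2 and 16.6%. The thinned share also differed between replicate numbers, at 17.72% in Ctrl-1, 8.87% in Ctrl-2 and 11.09% in Ctrl-3. Ctrl-1 lay above Sema-2 (14.53%) and Sema-3 (15.02%).

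Cells with a high interferon score made up 6.79% of LPS-3, while the 3 LPS cultures together had 3.57 ± 2.81%, Ctrl 1.27 ± 0.46%, Sema 1.04 ± 0.541% and SemaLPS 2.32 ± 0.489%. The median interferon score per thinned cell was 6.0 in LPS-3 and 3.0 in every other culture, so that the difference was not confined to the high-scoring cells. Genes of the stromal list were near the floor, and 3 of the 7 were measurable. Their means without TMM scaling were highest in Ctrl cultures, LUM at 4.59 CPM against 0.0368 in Sema, 0.23 in LPS and 0.0738 in SemaLPS. No level per culture is given for LUM, so that a single Ctrl culture may carry its mean. In SemaLPS against LPS the lymphocyte list (3 measurable genes, none past edgeR's test, where 827 of all genes had an unadjusted p under 0.05 and DESeq2 called 9) had a median of −0.64 (adjusted p = 0.00533, and adjusted p = 0.0655 with an estimated correlation). Apart from NKG7 its genes were near the floor too, such as GNLY at 0.683 CPM in LPS and 0.425 in SemaLPS cultures without TMM scaling. NKG7 stood at 23.5 and 21.6, so that the median does not show a change of lymphocytes.

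Splits of the 6 cultures of a contrast number 10, too few for a share under 0.05. For genes without the block the real values were 2, 8935, 2 and 9245 in Sema against Ctrl, LPS against Ctrl, SemaLPS against LPS and SemaLPS against Sema, the highest others 0 each, and 1 split, the real one, gave as many. With the block they were 513, 9851, 281 and 10232, the highest others 1, 0, 3 and 0, again with 1 split giving as many. For lists without the block the real values were 6, 5, 11 and 8, the highest others 9, 9, 10 and 10, and 4, 8, 1 and 2 splits gave as many. With the block they were 7, 5, 13 and 7, the highest others 7, 10, 9 and 9, and 3, 6, 1 and 5 splits gave as many.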
